A study of Mus musculus with 8 samples.

How the data were processed

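RNA was sequenced from fluorescent cells sorted from the cochlear nucleus of mouse embryos at stage E18.5. The cochlear nucleus is the first relay of the auditory pathway in the hindbrain. Cells were marked by a tdTomato reporter switched on by Cre recombinase under control of Math1, also called Atoh1, a transcription factor of the rhombic lip. Per the labels' protocols, each sample held 30000 sorted cells from a pool of 3 littermate embryos, and every sample came from a different mother, so the samples of a group are biologically separate. Libraries were made from 2 ng of total RNA with the TotalScript kit, which was primed with poly-A and random primers, and were amplified for 14 PCR cycles. The 8 libraries were pooled and run on 3 lanes of a HiSeq2500, per the labels' protocols. Neither the labels nor the table state that the libraries or the counting kept the strand.

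The authors deposited a single table of raw read counts per Ensembl gene, not normalised, together with a length per gene that the file header calls width. The build was mm10 and base calls came from bcl2fastq 1.8.4, per the submitters' processing notes. The aligner, the counting program and the annotation release were not given in the sources used here. The table held 39017 genes, of which 37607 were matched to a symbol. Column headings showed the group and a running number from 1 to 8, but not the replicate number in the sample titles. Columns were therefore assigned to a group only, and libraries are named here by group and heading number, as mutant 1 to mutant 4 and wild type 5 to wild type 8. Positions are those of GENCODE release M21 on the same build, and 19137 of the 19494 tested genes had one.

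Total counts ranged from 24789043 to 51118195 per library. Intervals for the level of a gene in a single library are exact two-sided Clopper-Pearson binomial intervals at 95%. For a count of 0 the limit of 3 counts is instead a one-sided bound at 95%. These cover counting error only, because PCR copies without molecular identifiers are not independent molecules. No 2 libraries agreed within sampling noise: the lowest chi-square per gene between any pair was 18.5.

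The main comparison set 4 mutant against 4 wild type libraries in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, scaled by TMM, and tested by the quasi-likelihood F test with robust dispersion, with no covariate and a Benjamini-Hochberg adjusted p below 0.05 as the threshold. The biological coefficient of variation was 23.2%. Standard errors of log2 fold changes are approximate. Each is the absolute fitted log2 fold change divided by the square root of its F statistic. Levels are given as TMM-scaled CPM (counts scaled to a common library total), as mean and SD over 4 libraries. Before the data were examined, 29 gene lists were fixed and tested with camera in limma 3.58.1 at a preset correlation of 0.01, with fry and with the correlation estimated per list beside it. Estimating the correlation also ties the degrees of freedom of camera to the 8 libraries, in place of the number of genes. A higher p there is therefore not due to correlation alone. With estimated correlations the adjustment gave many lists the same adjusted p of 0.542. Their unadjusted camera p differed, for example 0.0596 for the Pbx, Meis and Pknox list and 0.355 for the astrocyte list. Library scores of a list are means of log2 CPM with a prior count of 2. Single measures per library were compared by an exact two-sided permutation test over the 70 splits of 8 libraries, for which the smallest possible p is 0.0286.

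The genes named were also set by a rule fixed before the data were examined. The rule took Hoxa2 and Hoxb2, their neighbours Hoxa3, Hoxb1 and Hoxb3, and the 12 largest rises and 12 largest falls past the threshold with an average log2 CPM of at least 1 and no overlap between the groups. Gene models with provisional names were counted and not named. From each list it took up to 4 members that passed over all genes or when adjusted over the list alone, or else the 2 members with the smallest p as values only. All tested members of the Hox list could be named. A few genes that the rule took are not reported here, and counts over lists include them. Scaling moved the median log2 fold change of all genes by at most 0.06.

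The test was tested on simulated data in which 200 genes were changed between the groups at the real depths. At a fold of 1.5, 2% of the changed genes were recovered. At a fold of 2 the share was 54%, and at a fold of 4 it was 85.5%. Wrong calls made up 50% of the 8 calls at a fold of 1.5, 6.9% of the 116 calls at a fold of 2 and 7.57% of the 185 calls at a fold of 4. These shares are for the comparison of mutant with wild type, with 19045, 19108 and 19085 genes tested. Genes were drawn independently, without variation shared between genes across libraries. The shares therefore need not carry over to the real calls. After seeing the data, the simulation at a fold of 2 was also split by expression and repeated at 0.25 and 4 times the depth with the same dispersions, with 15435 and 19493 genes tested.

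Alternatives covered other scalings, other filters, dispersion without the robust option, DESeq2 1.42.0, limma-voom with and without sample quality weights, 1 surrogate variable from sva 3.50.0, removal of mitochondrially encoded and haemoglobin genes, each library left out in turn, an adjusted p below 0.1, and a test against a fold of 1.2. Added after seeing the data were a covariate for Y-linked expression, the removal of mutant 1, wild type 5 and wild type 6 together, and the Hox list without Hoxb1 and Hoxb2. The replicate number planned as a block could not be used.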

Results

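The transcriptome of Math1-lineage cells of the cochlear nucleus was compared between wild type embryos and embryos in which the Hox genes Hoxa2 and Hoxb2, transcription factors that pattern the hindbrain, were conditionally targeted. The study's stated purpose was to examine what these factors do in a subset of cochlear nucleus cells. There were 4 wild type and 4 mutant libraries from stage E18.5. The sample titles describe the mutant as heterozygous for the conditional Hoxa2 allele and homozygous for that of Hoxb2, whereas the design text describes both as homozygous, and this disagreement is left open. Total counts were 37057679, 24789043, 34775363 and 40050010 in wild type 5 to 8, and 30374217, 26299105, 51118195 and 39419386 in mutant 1 to 4.

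Of the targeted genes Hoxb2 fell, whereas Hoxa2 did not pass the test. Hoxb2 (ENSMUSG00000075588, chromosome 11, 96350525 to 96354012, mm10) fell from 40.1 ± 4.41 CPM (SD, n = 4) in wild type to 5.02 ± 1.49 CPM (SD, n = 4) in mutant libraries, a log2 fold change of -3.00 (SE 0.199, edgeR adjusted p = 3.76e-05; exact two-sided permutation p = 0.0286, the smallest these 8 libraries allow). Raw Hoxb2 counts were 1456, 1198, 1311 and 1538 in wild type 5 to 8 and 208, 97, 194 and 210 in mutant 1 to 4. Hoxa2 (ENSMUSG00000014704, chromosome 6, 52162417 to 52164831) was at 43.2 ± 10.99 CPM (SD, n = 4) in wild type and 26.7 ± 15.7 CPM (SD, n = 4) in mutant libraries, a log2 fold change of -0.70 (SE 0.401, edgeR adjusted p = 0.506, exact two-sided permutation p = 0.114) that did not pass. Its level was 30.8, 55.1, 49.2 and 37.7 CPM in wild type 5 to 8 and 19.9, 48.0, 11.1 and 27.8 CPM in mutant 1 to 4, so that mutant 2 lay within the wild type range. The Hoxb2 gene lies inside the antisense gene Hoxb3os, at 115 CPM in wild type and 55.0 CPM in mutant libraries, and without strand the reads of the overlapping part cannot be assigned to either. The labels do not say which part of each gene the conditional allele removes.

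Hoxb1 (ENSMUSG00000018973, chromosome 11, 96365752 to 96368256), the neighbour of Hoxb2 and in the embryo a marker of rhombomere 4, rose more than any other named gene. Wild type libraries held 7, 12, 4 and 8 counts and mutant 1 to 4 held 2878, 1933, 4588 and 3113. The level was 0.241 ± 0.155 CPM (SD, n = 4) in wild type and 85.9 ± 7.71 CPM (SD, n = 4) in mutant libraries, a log2 fold change of 8.55 (SE 0.261, edgeR adjusted p = 8.37e-09). In wild type 7, the lowest, the exact 95% interval ran from 0.0313 to 0.295 CPM of the unscaled total, and in mutant 2 from 70.3 to 76.9. Hoxa3 had a log2 fold change of 0.30 (SE 0.411), and Hoxb3 of -0.69 (SE 0.509), with edgeR adjusted p of 0.784 and 0.601. The sign for Hoxa3 turned to -0.23 without mutant 1, in which it stood at 67.2 CPM. Without mutant 1 Hoxb3 passed, at -1.47 (edgeR adjusted p = 0.0138).

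**Figure D1:**
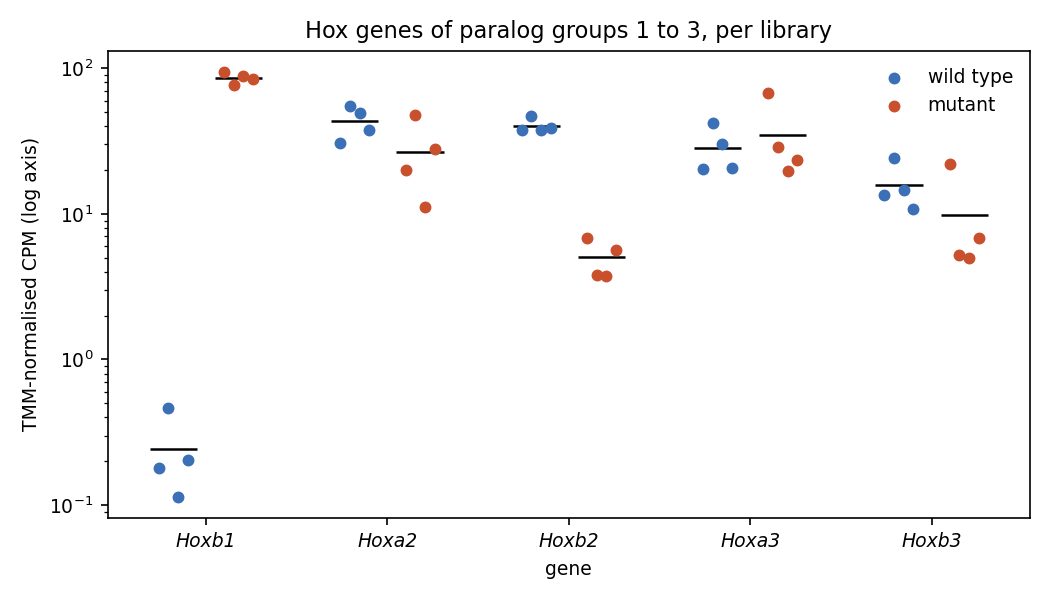
TMM-scaled CPM on a log axis for 5 Hox genes, with a point per library and a bar at the mean of each group of 4. Hoxb1 lies at 76.1 to 94.2 CPM in mutant libraries against at most 0.467 CPM in wild type, and Hoxb2 at 3.77 to 6.81 CPM against 37.4 to 46.6 CPM.

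Of 15 listed Hox genes of paralog groups 1 to 5, 12 were tested, 1 rose, 1 fell and 10 did not pass, and 2 rose and 1 fell adjusted over the list alone. Hoxa4, Hoxc4, Hoxd3, Hoxb4 and Hoxb5 had group means of at most 6.04 CPM and were uneven between libraries. Log2 fold changes were 0.41 for Hoxa4 (SE 0.657), 0.49 for Hoxc4 (SE 0.795), -0.23 for Hoxd3 (SE 0.667), 0.03 for Hoxb4 (SE 0.693) and 0.03 for Hoxb5 (SE 1.31). The sign of each turned with single libraries left out: Hoxa4 without mutant 1, Hoxc4 without mutant 2, Hoxd3 without wild type 6, mutant 3 or mutant 4, Hoxb4 without mutant 1 or wild type 5, 7 or 8, and Hoxb5 without mutant 2 or wild type 5 or 8. Hoxb4 and Hoxb5 also turned when scaled by library size only. Hoxa5 stood at 14.3 CPM in mutant 2 and at most 0.74 CPM in any other library, with a log2 fold change of 3.26 (SE 1.66) that became -0.58 without mutant 2. The list passed as higher in mutants (camera adjusted p = 0.00219), with an adjusted p = 0.542 with an estimated correlation, and its adjusted p was 0.948 without Hoxb1 and Hoxb2. The adjusted p of the list was 0.405 without mutant 1, 0.138 without mutant 1, wild type 5 and wild type 6 together, and 0.976 with limma-voom with quality weights.

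Across all genes, 19494 were tested and 70 passed, 28 higher and 42 lower in mutant libraries (edgeR, adjusted p below 0.05). All 70 had groups that did not overlap, as did 6.17% of tested genes, where chance gives 2.86%. At an unadjusted p below 0.05 there were 2439 genes, and the median log2 fold change of tested genes was -0.01. The number of calls depended on single libraries. It was 544 without mutant 1, 33 without mutant 2, 36 without mutant 3, 26 without mutant 4, 36 without wild type 5 and 32 without wild type 8. Other tools also moved it: DESeq2 called 497 genes and limma-voom with sample quality weights called 233. With mutant 1, wild type 5 and wild type 6 left out together, an alternative chosen after seeing the data, 171 genes passed.

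Besides Hoxb1, the largest rises among named genes with an average log2 CPM of at least 1 ran from 1.25 for Etv1 to 2.34 for Zfp984 on the log2 scale. Cyp26b1 (ENSMUSG00000063415, chromosome 6, 84571414 to 84593908), which degrades retinoic acid, rose from 6.34 ± 1.81 to 17.2 ± 2.28 CPM (SD, n = 4), a log2 fold change of 1.44 (SE 0.204, edgeR adjusted p = 0.0108). Cacna1g (ENSMUSG00000020866, chromosome 11, 94408391 to 94474198), a T-type calcium channel subunit, rose from 32.5 ± 7.03 to 79.6 ± 11.2 CPM (SD, n = 4), or 1.29 on the log2 scale (SE 0.165, edgeR adjusted p = 0.00619). Tmem132b rose by 1.52 (SE 0.179) and Irak1bp1 by 1.37 (SE 0.146) on the log2 scale. The extracellular matrix protein Svep1 rose by 1.99 (SE 0.312), the zinc finger gene Zfp984 by 2.34 (SE 0.412), the cadherin-related Cdhr1 by 1.77 (SE 0.255) and the globin Cygb by 1.45 (SE 0.259). Mctp1 rose by 1.35 (SE 0.238), the neuronal amino acid transporter Slc6a17 by 1.28 (SE 0.199) and the ETS factor Etv1 by 1.25 (SE 0.232). Adjusted p for these genes lay between 0.00177 for Irak1bp1 and 0.0499 for Etv1. Of 37 named genes past the threshold, 11 overlap another tested gene and may share reads with it, among them Zfp984, Svep1, Cygb, Mctp1 and Calml4.

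The largest falls with the same minimum, Hoxb2 among them, ran from -1.42 for Eya1 to -3.80 for Pde1c on the log2 scale. Pde1c (ENSMUSG00000004347, chromosome 6, 56069804 to 56569103), a calmodulin-dependent phosphodiesterase, fell from 244 ± 51.8 to 17.6 ± 12.7 CPM (SD, n = 4), a log2 fold change of -3.80 (SE 0.46, edgeR adjusted p = 0.0145). Me1 (ENSMUSG00000032418, chromosome 9, 86581371 to 86695953), the cytosolic malic enzyme, fell from 55.1 ± 7.04 to 12.2 ± 5.09 CPM (SD, n = 4), a log2 fold change of -2.18 (SE 0.24, edgeR adjusted p = 0.00415). The log2 fold changes were -1.97 for the glycogen phosphorylase Pygl (SE 0.26), -1.66 for the glutathione transferase Gsta4 (SE 0.261) and -1.62 for the prostaglandin D synthase Hpgds (SE 0.266). Rassf9 changed by -1.88 (SE 0.337), Slc35f4 by -1.60 (SE 0.245), the collagen Col8a1 by -1.52 (SE 0.284), Calml4 by -1.44 (SE 0.225) and Clrn1, an Usher syndrome gene, by -1.44 (SE 0.202). Eya1 (ENSMUSG00000025932, chromosome 1, 14168954 to 14310235), a transcriptional coactivator with phosphatase activity, fell from 12.4 ± 1.11 to 4.67 ± 1.04 CPM (SD, n = 4), or -1.42 on the log2 scale (SE 0.181, edgeR adjusted p = 0.00619). Of these 24 largest changes, 9 held in all 21 alternatives, namely Hoxb2, Hoxb1, Tmem132b, Cyp26b1, Irak1bp1, Cacna1g, Me1, Pygl and Eya1. The other 15 kept their direction and lost the threshold in some alternatives, with an adjusted p of up to 0.18: 11 without wild type 5, 6 without wild type 6, 5 without wild type 7, 13 without wild type 8, 11 without mutant 2, 12 without mutant 3 and 15 without mutant 4. Upper quartile scaling and a filter of at least 1 CPM in 4 libraries each ended 6 of these calls, 1 surrogate variable ended 5, limma-voom and the removal of mutant 1, wild type 5 and wild type 6 together ended 3 each, and the remaining alternatives ended at most 2.

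**Figure D2:**
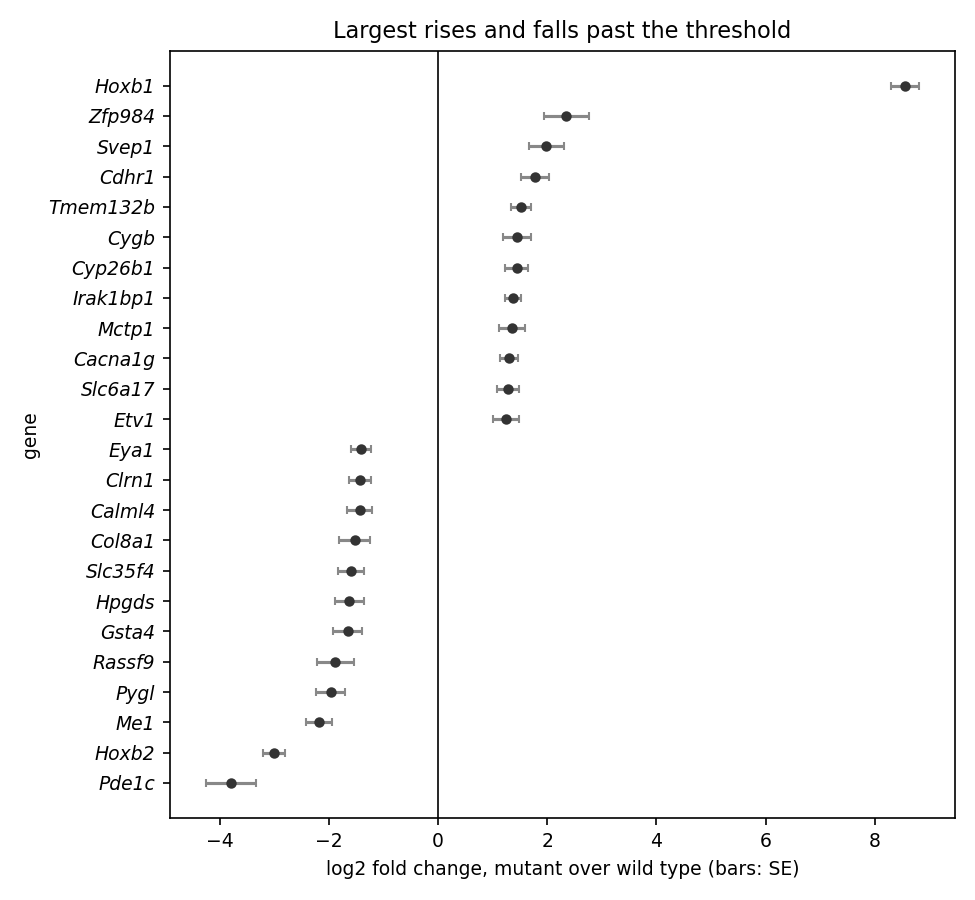
Fitted log2 fold change, mutant over wild type, with SE bars, for the 12 largest rises and 12 largest falls past the threshold among genes with an approved-style name, an average log2 CPM of at least 1 and no overlap between groups of 4 libraries. Values run from -3.80 for Pde1c to 8.55 for Hoxb1, and called genes below that minimum, such as C1qa at -3.45, are not drawn.

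Of 9 tested Pbx, Meis and Pknox genes, which encode transcription factors that act with Hox proteins, Meis1 and Meis2 fell and 7 did not pass, and 3 of the 9 had a positive fold change. Adjusted over the list alone, 2 fell and 1, Pbx4, rose. Meis1 fell from 503 ± 55.3 to 332 ± 17.1 CPM (SD, n = 4), a log2 fold change of -0.60 (SE 0.107, edgeR adjusted p = 0.0412). Meis2 fell from 135 ± 22.2 to 61.8 ± 18.0 CPM (SD, n = 4), or -1.13 on the log2 scale (SE 0.201, edgeR adjusted p = 0.0441). Pbx4 was at 4.46 CPM in wild type and 7.12 CPM in mutant libraries, a log2 fold change of 0.68 (SE 0.183, edgeR adjusted p = 0.162). The antisense gene Gm16140, which overlaps Meis1, also fell (log2 fold change -0.90, adjusted p = 0.0118). The list passed as lower (camera adjusted p = 0.0497), with an adjusted p = 0.542 with an estimated correlation and 0.0198 by fry. With its estimated correlation of -0.0714 the list had an unadjusted camera p of 0.0596, against 0.0257 at the preset correlation. An estimate below 0 does not raise the p, so that rise comes from the fewer degrees of freedom. The list's call ended without wild type 7, wild type 8, mutant 1 or mutant 4 (adjusted p 0.171, 0.0827, 0.156 and 0.0788), with DESeq2 size factors (0.0504), upper quartile scaling (0.0548), no low-count filter (0.0808), the non-robust fit (0.0501) and limma-voom with quality weights (0.12). Its adjusted p was 0.0532 when the Hox list was shortened, which changes only the adjustment over lists and not this list's own test. The Meis1 call ended without wild type 5, 7 or 8 or mutant 2, 3 or 4, and that of Meis2 without wild type 6, 7 or 8 or mutant 3 or 4, with upper quartile scaling and with the CPM filter, with adjusted p of up to 0.156 and 0.146.

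Among genes of the Atoh1 lineage and of cochlear nucleus excitatory neurons, 21 were tested and 1 fell, while adjusted over the list alone 2 fell and 1 rose. Nhlh1, a helix-loop-helix factor of young neurons, fell from 89.2 ± 5.61 to 46.3 ± 6.86 CPM (SD, n = 4), a log2 fold change of -0.95 (SE 0.119, edgeR adjusted p = 0.00603). The homeobox gene Barhl2 had -0.67 (SE 0.164) and the calcium-binding protein Calb2 1.06 (SE 0.293), and both passed over all genes without mutant 1 (adjusted p 0.0171 and 0.0182). The list itself did not pass (camera adjusted p = 0.101), but passed as lower without wild type 5 (0.0205) or mutant 2 (0.0105), without mutant 1, wild type 5 and wild type 6 together (0.0393), and with a filter of at least 1 CPM in 4 libraries (0.0277). Of 18 tested granule and unipolar brush cell genes, Etv1 rose and Sema6a fell, also adjusted over the list alone, and the list did not pass (adjusted p = 0.688). In the list of hindbrain segment and retinoic acid genes, with 17 tested, only Cyp26b1 passed, and the list had an adjusted p of 0.722. None of 16 midbrain and rhombomere 1 genes passed, also adjusted over the list alone, where En2 had 0.78 (SE 0.353) and Otx2 -0.32 (SE 0.159), and the list had an adjusted p of 0.453. By edgeR 1 of these 16 had an unadjusted p below 0.05, and 0 passed with DESeq2 or limma-voom. The tendency of the granule list turned lower without wild type 6 or mutant 3 (adjusted p 0.643 and 0.746), and that of the hindbrain segment list turned higher without wild type 6 (0.875).

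Of the 3 lists of axon guidance genes none passed, and Sema6a was the only member past the threshold over all genes by edgeR. The semaphorin list had 31 tested members, of which 1 fell, and 2 fell and 1 rose adjusted over the list alone. Sema6a fell from 356 ± 34.97 to 227 ± 14.6 CPM (SD, n = 4), a log2 fold change of -0.65 (SE 0.105, edgeR adjusted p = 0.0251), and Plxnc1 had -0.42 (SE 0.0928) and Sema4f 0.71 (SE 0.19). The Sema6a call ended without wild type 6, 7 or 8 or mutant 2, 3 or 4, with an adjusted p of up to 0.108. Of 20 tested netrin, slit and draxin genes none passed over all genes, and adjusted over the list alone Slit2 was lower at -1.06 (SE 0.23) and Unc5c higher at 0.61 (SE 0.175). Over all genes Slit2 passed without mutant 1 (adjusted p = 0.00202), without mutant 1, wild type 5 and wild type 6 together (0.00913), with the Y-linked covariate (0.0328), with DESeq2 (0.00119) and with limma-voom with quality weights (0.0179). Without mutant 1 Unc5c and Sema4f passed as well (0.0302 and 0.0483). None of 22 Eph receptors and ephrins passed either way, where Epha10 had 0.71 (SE 0.191) and Efnb2 -0.50 (SE 0.147). At an unadjusted edgeR p below 0.05 there were 7 netrin and 3 Eph genes, and DESeq2 called 2 and 1. The adjusted p of the semaphorin, netrin and Eph lists was 0.309, 0.846 and 0.403, and the netrin list tended lower without mutant 1 (adjusted p = 0.405). For the netrin list the median and the mean, and for the semaphorin list the median, had the opposite sign to the test.

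The lists of cadherins and of synaptic adhesion genes passed as higher in mutants at the preset correlation (camera adjusted p = 0.000266 and 0.00912). Each had an adjusted p = 0.542 with an estimated correlation. Among 26 classical cadherins and protocadherins 18 had a positive fold change, none passed over all genes, and 7 passed as higher adjusted over the list alone. By edgeR 8 had an unadjusted p below 0.05, and DESeq2 called 5, limma-voom 0 and limma-voom with quality weights 2. Log2 fold changes were 0.96 for Cdh11 (SE 0.193), 0.70 for Cdh4 (SE 0.149), 1.02 for Cdh13 (SE 0.213) and 1.44 for Pcdh11x (SE 0.404). These 4 passed over all genes without mutant 1 (adjusted p 0.00853, 0.0491, 0.0132 and 0.0128), and Cdh13 also without wild type 7 (0.0217). Among 36 immunoglobulin and synaptic adhesion genes 26 were positive, 1 fell, and adjusted over the list alone 3 rose and 1 fell. The leucine-rich repeat adhesion protein Flrt3 fell from 41.0 ± 2.29 to 20.6 ± 0.561 CPM (SD, n = 4), a log2 fold change of -0.99 (SE 0.102, edgeR adjusted p = 0.0016), against the direction of its list. Lrrtm4 had 0.96 (SE 0.21), Lrrtm3 0.79 (SE 0.213) and Flrt1 0.83 (SE 0.231), of which Lrrtm4 and Lrrtm3 passed over all genes without mutant 1 (adjusted p 0.00672 and 0.00943). The synaptic adhesion call ended without wild type 6, mutant 2 or mutant 4 (adjusted p 0.0839, 0.0693 and 0.0569), and without mutant 1, wild type 5 and wild type 6 together (0.069). The mean log2 CPM of that list was lowest in these 3 libraries, at most 5.50 against at least 5.54 in the others. Cadherin scores did not split this way, with wild type 8 at 2.88 below mutant 1 at 3.02. Flrt3 overlaps Macrod2, at 39.4 and 34.5 CPM.

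Lists of ion channels, receptors and vesicle proteins passed as higher in mutants at the preset correlation. With an estimated correlation the adjusted p = 0.542 for 4 of these 5 lists and 0.553 for the glutamate receptors. Positive fold changes were found in 20 of 25 sodium and calcium channel genes, 21 of 29 potassium and HCN channel genes, 17 of 24 glutamate receptor genes, 17 of 20 GABA-A and glycine receptor genes and 24 of 30 vesicle release genes. The median log2 fold changes were 0.31, 0.25, 0.36, 0.33 and 0.21, and the camera adjusted p values 0.000508, 0.0064, 0.0167, 0.000308 and 0.000508. Cacna1g was the only member past the threshold over all genes by edgeR. At an unadjusted p below 0.05 there were 5, 9, 5, 6 and 8 members in the same order, and DESeq2 called 2, 1, 1, 2 and 3. Adjusted over the list alone, 1 sodium and calcium channel gene, 2 GABA-A and glycine receptor genes and 3 vesicle release genes rose, and no member of the other lists passed. Log2 fold changes were 0.66 for Gabra4 (SE 0.143), 0.91 for Gabrb1 (SE 0.206), 1.09 for Syt7 (SE 0.208), 2.46 for Syt4 (SE 0.454) and 0.78 for Rims1 (SE 0.213). They were 0.75 for Kcna6 (SE 0.226), 0.98 for Grm5 (SE 0.296) and 0.80 for Grin1 (SE 0.258). Without mutant 1 Gabra4, Gabrb1, Syt7, Syt4, Rims1 and Grm5 passed over all genes (adjusted p 0.0393, 0.0364, 0.00907, 0.00558, 0.0201 and 0.00558), and Syt7 also without wild type 7 (0.0301). Gabra4 and Gabrb1 overlap, and so may share reads. Scores, the mean log2 CPM of a list, were lowest in wild type 5, wild type 6 and mutant 1 for the sodium and calcium channel, the GABA-A and glycine receptor and the vesicle release lists, at most 4.64, 3.25 and 5.52 against at least 4.73, 3.42 and 5.59 in the other libraries. In the same comparison the inhibitory neuron list passed as higher and the microglia and astrocyte lists as lower at the preset correlation (camera adjusted p 0.0167, 0.000393 and 0.0064), and each had an adjusted p = 0.542 with an estimated correlation. The inhibitory neuron call ended without wild type 5, mutant 2 or mutant 4, and the astrocyte call without wild type 6, mutant 3 or mutant 4, with adjusted p of up to 0.181 and 0.129. The potassium channel call ended without mutant 4 (adjusted p = 0.054), and the glutamate receptor call without wild type 5, mutant 2 or mutant 4 (0.0737, 0.24 and 0.153). Of 10 neurotrophin genes none passed either way (list adjusted p = 0.489), where Ret had 0.57 (SE 0.186) and Ntrk2 0.32 (SE 0.168). By edgeR 1 of the 10 had an unadjusted p below 0.05, and DESeq2 and limma-voom called 0.

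**Figure D3:**
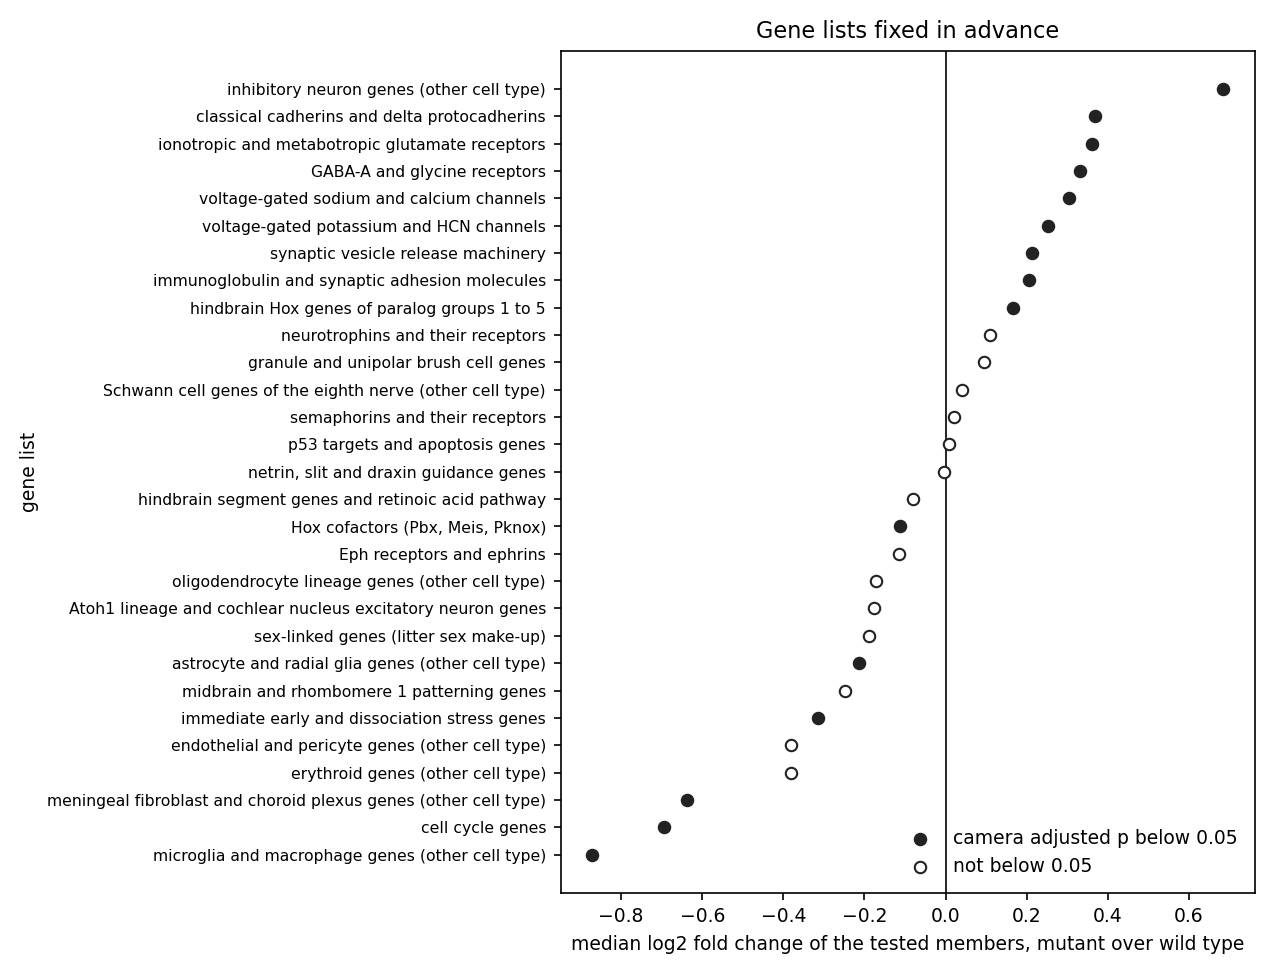
Median log2 fold change, mutant over wild type, of the tested members of each of 29 gene lists. Filled points mark the 15 lists with a camera adjusted p below 0.05 at the preset correlation, 9 higher and 6 lower, and 0 of them passed with an estimated correlation, where 0 of 29 had an unadjusted p below 0.05, directional fry called 1 and mixed fry 16.

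The cell cycle list passed as lower, with 24 of 26 negative and a median of -0.70 on the log2 scale (camera adjusted p = 0.000198, adjusted p = 0.542 with an estimated correlation). No single member passed, also adjusted over the list alone. Mcm2 had -0.71 (SE 0.206) and Mcm4 -0.48 (SE 0.151), and without mutant 1 Mcm2 passed over all genes (-0.88, edgeR adjusted p = 0.0328). The estimated correlation of this list was 0.906. Its mean log2 CPM was 5.66 in wild type 5, 5.70 in wild type 6 and 5.31 in mutant 1, against 3.93 to 4.70 in the other libraries. These 3 libraries had the lowest Xist levels and the lowest scores on the first principal component, for which they were removed together. The call ended without mutant 1, wild type 5 and wild type 6 together (adjusted p = 0.0955). The list of immediate early and dissociation stress genes also passed as lower, with 17 of 21 negative (camera adjusted p = 0.00912, adjusted p = 0.542 with an estimated correlation). Ier3 had -0.59 (SE 0.207) and Zfp36 -0.78 (SE 0.298), no member passed either way, and the call ended without wild type 6 (adjusted p = 0.134). The mean log2 CPM of that list was also highest in the same 3 libraries, at least 3.63 against at most 3.35. Of 17 p53 and apoptosis genes none passed either way (list adjusted p = 0.846), where Hrk had -0.56 (SE 0.189) and Phlda3 0.81 (SE 0.352). The tendency of this list turned when scaled by library size only and without wild type 5, 6 or 7 or mutant 1 (adjusted p 0.978, 0.846, 0.822, 0.93 and 0.65). At an unadjusted edgeR p below 0.05 there were 3 cell cycle, 3 immediate early and 2 p53 genes, and DESeq2 and limma-voom called 0.

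The microglia list passed as lower, with 9 of 11 tested negative (camera adjusted p = 0.000393, adjusted p = 0.542 with an estimated correlation). C1qa fell from 2.36 ± 1.19 to 0.203 ± 0.104 CPM (SD, n = 4), a log2 fold change of -3.45 (SE 0.5, edgeR adjusted p = 0.0115), and 3 members fell adjusted over the list alone, where P2ry12 had -2.03 (SE 0.445) and Cx3cr1 -2.41 (SE 0.669). Over all genes these passed without mutant 1 (adjusted p 0.0351 and 0.0491), and P2ry12 also without wild type 8 (0.0424). The C1qa call ended without mutant 2 or mutant 4 (edgeR adjusted p = 0.0525 and 0.0527), without mutant 1, wild type 5 and wild type 6 together (0.0697) and with limma-voom (0.0749), and the list's call ended with a filter of at least 1 CPM in 4 libraries (0.645). The astrocyte and radial glia list passed as lower, with 17 of 19 negative (camera adjusted p = 0.0064, adjusted p = 0.542 with an estimated correlation), and adjusted over the list alone 1 fell, Glul at -0.45 (SE 0.11). Their call ended without wild type 6, mutant 3 or mutant 4 (adjusted p 0.0852, 0.128 and 0.129), and their mean log2 CPM was highest in wild type 5, wild type 6 and mutant 1, at least 4.71 against at most 4.63. Meningeal and choroid plexus genes had 9 of 13 negative (camera adjusted p = 0.0491, adjusted p = 0.542 with an estimated correlation), and 2 fell adjusted over the list alone, Cldn1 at -1.64 (SE 0.421) and Igf2 at -1.48 (SE 0.438), of which Cldn1 passed over all genes without mutant 1 (adjusted p = 0.0276). That call ended without wild type 5, 6 or 7 or mutant 1, 2 or 4 (adjusted p 0.183, 0.145, 0.0666, 0.0507, 0.24 and 0.0656) and without mutant 1, wild type 5 and wild type 6 together (0.574). It also ended with library size or upper quartile scaling (0.105 and 0.0652), the CPM filter (0.456), the non-robust fit (0.0501), the Y-linked covariate (0.0671) and quality weights (0.0948). When the Hox list was shortened the adjusted p was 0.0528, through the adjustment over lists alone. The inhibitory neuron list passed as higher, with 12 of 15 positive and a median of 0.68 (camera adjusted p = 0.0167, adjusted p = 0.542 with an estimated correlation), and 1 rose adjusted over the list alone. Their call ended without wild type 5, mutant 2 or mutant 4 (adjusted p 0.101, 0.181 and 0.054), and without mutant 1, wild type 5 and wild type 6 together (0.0542). At an unadjusted edgeR p below 0.05 there were 3 astrocyte, 5 meningeal and 5 inhibitory neuron genes, and DESeq2 called 1, 2 and 1.

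The remaining lists of other cell types did not pass, and by edgeR with all 8 libraries none of their members passed over all genes or adjusted over the list alone. The list adjusted p was 0.0734 for 15 oligodendrocyte lineage genes, 0.489 for 7 Schwann cell genes, 0.0714 for 16 endothelial and pericyte genes, 0.177 for 4 erythroid genes and 0.846 for 5 sex-linked genes. At an unadjusted edgeR p below 0.05 there were 4, 1, 2, 1 and 0 members in that order, and DESeq2 called 1 oligodendrocyte gene and 0 of the others. Hbb-bs passed as lower with limma-voom with quality weights (-4.38, adjusted p = 0.0482), and Opcml with DESeq2 (adjusted p = 0.0244) and without mutant 1, wild type 5 and wild type 6 together (-1.36, edgeR adjusted p = 0.0241). The oligodendrocyte list passed as lower without wild type 5 or 8 or mutant 2, 3 or 4 (adjusted p 0.0423, 0.00516, 0.03, 0.0452 and 0.00602), the endothelial list without wild type 5 or 8 or mutant 2 (0.0352, 0.00244 and 0.00462), and the erythroid list without mutant 3 (0.0168). With no low-count filter the oligodendrocyte and erythroid lists passed as lower (0.0314 and 0.0119), and with the CPM filter the endothelial list did (0.0241). Examples were Sox10 at -1.28 (SE 0.39), Opcml at -1.03 (SE 0.322), Cldn19 at -1.11 (SE 0.352), Prx at -0.28 (SE 0.328), Notch3 at -0.81 (SE 0.249), Flt1 at -1.02 (SE 0.459), Hbb-bs at -2.49 (SE 0.938) and Slc4a1 at -0.67 (SE 0.585). Ddx3y had -0.54 (SE 1.73) and Uty -0.45 (SE 1.68), and the mean log2 CPM of Y-linked genes ran from -2.86 to 6.25 in wild type and from -3.64 to 6.21 in mutant libraries. The sex-linked list turned when scaled by library size only and without wild type 5 or 6 or mutant 3 (adjusted p 0.97, 0.953, 0.946 and 0.56), Ddx3y and Uty without wild type 5 (0.11 and 0.27). The Schwann list had a median of opposite sign to its test.

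None of 6 measures per library passed an exact permutation test between genotypes. Mitochondrially encoded genes took 11.9 ± 1.25% of counts in wild type and 12.7 ± 1.17% in mutant libraries (SD, n = 4, exact two-sided permutation p = 0.371, adjusted p = 0.6 over 6 measures). The 10 most abundant genes took 22.6 ± 1.45% and 24.3 ± 3.66% (SD, n = 4, exact permutation p = 0.4, adjusted p = 0.6), a difference above the SD of wild type and below that of mutant libraries. Genes with at least 5 counts numbered 22780 ± 934 and 21978 ± 1306 (SD, n = 4, exact permutation p = 0.343, adjusted p = 0.6). The first principal component held 34.4% of the variance. Its scores were -24.0 ± 27.7 in wild type and 24.0 ± 31.6 in mutant libraries (SD, n = 4, exact permutation p = 0.0857, adjusted p = 0.514), a difference above either SD, with scores that overlapped between genotypes.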

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

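Padi4 was the only gene here chosen after its values were seen. In a group of 4 libraries, a library was singled out when its gap to the nearest of the others, divided by the whole range, exceeded Dixon's 95% critical value for 4 samples. This was so in 20 of 258 groups examined, or 7.75%, and chance gives about 5%. The ratios below follow that definition.

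Among Hox genes, mutant 2 held Hoxa5 at 14.3 CPM against at most 0.54 in the other mutant libraries (ratio 0.962) and Hoxb5 at 5.47 CPM against at most 0.982 (ratio 0.833). Mutant 1 held Hoxb3 at 22.1 CPM against 4.95 to 6.81 (ratio 0.892). Wild type 6 held Hoxb2 at 46.6 CPM against 37.4 to 38.9 (ratio 0.837) and Hoxa5 at 0.74 CPM against at most 0.315 (ratio 0.83).

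Among genes past the threshold, mutant 1 kept Pde1c at 36.5 CPM against 10.2 to 12.9 in the other mutant libraries (ratio 0.897). Mutant 2 held Me1 at 19.8 CPM against 8.61 to 10.3 (ratio 0.845), Cyp26b1 at 20.6 CPM against 15.6 to 16.3 (ratio 0.851), and Padi4 at 0.197 CPM against 0.0971 to 0.108 (ratio 0.891). A level of 3 counts is 0.0587 CPM of the unscaled total in mutant 3 and 0.114 CPM in mutant 2. The Padi4 ratio therefore rests on few counts. Wild type 7 held Zfp984 at 1.89 CPM against at most 0.617 in the other wild type libraries (ratio 0.871).

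Among the remaining genes, Otx2 was 609 CPM in mutant 3 against 450 to 468 (ratio 0.883), Calb2 16.3 CPM in wild type 7 against 9.64 to 10.1 (ratio 0.931), and Ret 9.27 CPM in wild type 6 against 6.46 to 6.84 (ratio 0.867). En2 was 1.67 CPM in wild type 8 against 4.06 to 4.47 (ratio 0.853), and Igf2 3.57 CPM in wild type 8 against 9.23 to 10.1 (ratio 0.863). Zfp36 was 4.19 CPM in mutant 1 against 2.38 to 2.44 (ratio 0.964), Sox10 0.837 CPM in mutant 4 against at most 0.393 (ratio 0.851), and Hbb-bs 0.544 CPM in mutant 3 against at most 0.0788 (ratio 0.855). The mean log2 CPM of the inhibitory neuron list was 1.02 in wild type 5 against 1.89 to 1.99 (ratio 0.895). That of the sex-linked list was -0.63 in mutant 3 against 5.47 to 6.37 (ratio 0.871).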

How the results depend on the processing

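No paired analysis was possible because the columns carry no replicate numbers. The covariate for the Y-linked level, the removal of mutant 1, wild type 5 and wild type 6 together, the shortened Hox list and the simulations by expression and depth were chosen after seeing the data. Unless stated, the cause was not tested.

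The 70 calls, 28 higher and 42 lower, stayed within 1.5 times under other scalings (58 to 76), the CPM filter (53), the non-robust fit (66), 1 surrogate variable (78), the Y-linked covariate (94), limma-voom (69) and removal of mitochondrial and haemoglobin genes (71). They were 214 (127 higher, 87 lower) with no low-count filter, 171 (95 and 76) without the 3 libraries together, 181 (97 and 84) at an adjusted p below 0.1, 38 (13 and 25) against a fold of 1.2, 497 (311 and 186) with DESeq2 and 233 (130 and 103) with quality weights. With 1 library left out they ranged from 26 to 544, with 11 to 336 higher and 15 to 208 lower. Without mutant 1 all 70 were shared, and without mutant 4, 25 were. Called lists ranged from 9 to 16 with 1 library left out, were 0 with an estimated correlation, 1 by directional fry and 16 by mixed fry, which tests for change in either direction.

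Hoxb2 kept its direction and call in all 21 alternatives (log2 fold change -3.18 to -2.88), and so did Hoxb1 (8.33 to 8.99). Hoxa2 stayed lower and uncalled in all 21 (-1.14 to -0.44, adjusted p 0.288 to 0.767). The mitochondrial share, the share of the 10 most abundant genes and the number of genes detected kept their direction and stayed uncalled. Over named genes and lists that were called, 630 and 255 values kept direction and call, 145 and 75 lost the call, and 0 turned. Of uncalled ones, 85 and 16 passed, and 32 and 22 turned. The 85 include 27 with DESeq2 and 22 without mutant 1.

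Those that turned were uncalled throughout, except the erythroid list, which passed as lower with no low-count filter (0.0119) and without mutant 3 (0.0168). Values are log2 fold changes for genes and, for lists, adjusted p with a minus sign where the list tended lower. With library size only, Hoxb4 was -0.0261, Hoxb5 -0.0503, the p53 list -0.978 and the sex-linked list 0.97. With the CPM filter the erythroid list was 0.989 and the p53 list -0.783. With 1 surrogate variable Hoxb5 was -0.24. With the Y-linked covariate Hoxb4 was -0.00439 and the netrin list -0.84. Without the 3 libraries together Hoxa3 was -0.0759, Slc4a1 0.22, Ddx3y 0.85, Uty 1.01, Hoxb4 -0.38, the midbrain list 0.933, the netrin list -0.496, the granule list -0.933 and the p53 list -0.404. With limma-voom Hoxa5 was -0.49, Hoxb4 -0.31 and Hoxb5 -0.81. With quality weights Ddx3y was 0.45, Uty 0.34, Hoxb4 -0.21, Hoxb5 -0.27, the p53 list -0.976 and the sex-linked list 0.676.

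With 1 library left out, ranges were -1.67 to 0.11 for Ddx3y, -1.37 to 0.27 for Uty, -0.99 to 0.54 for Hoxb4, -2.05 to 1.14 for Hoxb5, -1.26 to 0.17 for Hoxd3, -0.23 to 0.56 for Hoxa3, -0.16 to 1.08 for Hoxa4, -0.58 to 3.69 for Hoxa5 and -0.45 to 0.92 for Hoxc4. For lists they were -0.93 to 0.938 (p53), -0.93 to 0.953 (sex-linked), -0.95 to 0.875 (hindbrain segment), -0.746 to 0.946 (granule) and -0.405 to 0.982 (netrin).

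Genes were also drawn independently in the simulations by expression and depth. At a fold of 2 the test recovered 7.41% of changed genes in the lowest of 3 equal expression classes (up to 3.03 CPM). The share was 52.4% in the middle class and 95.3% in the highest. With dispersions held, 0.25 and 4 times the depth gave 49.5% and 55% of all changed genes, against 54%, and 1.85% and 5.56% in the lowest class, against 7.41%. In the lowest class these are 1 and 3 of 54 genes, against 4, too few to rank the depths. Thinned to the smallest library, the genes detected ranged from 19979 to 23465.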

Other observations

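The genes of the next paragraph and Zfp990, Padi4 and Zfp979 were chosen after their values were seen, and so were all tests below except the 2 counts over splits, the motor neuron markers and the gene length correction.

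Among the other called genes were Nr2f2, Id4, Cdon and Kcnn1. The nuclear receptor Nr2f2 rose from 523 to 888 CPM, a log2 fold change of 0.76 (SE 0.113, edgeR adjusted p = 0.0131), and Id4, an inhibitor of helix-loop-helix factors, rose from 20.7 to 48.8 CPM, or 1.24 (SE 0.173, edgeR adjusted p = 0.0105). Cdon, a co-receptor of hedgehog ligands, fell from 84.0 to 48.4 CPM, a log2 fold change of -0.79 (SE 0.0947, edgeR adjusted p = 0.00415). Kcnn1, a calcium-activated potassium channel, fell from 13.9 to 5.30 CPM, or -1.39 (SE 0.234, edgeR adjusted p = 0.0278). Id4 and Cdon held in all 21 alternatives. The Nr2f2 call ended without wild type 8, mutant 2 or mutant 4, and the Kcnn1 call without wild type 5, 7 or 8 or mutant 2, 3 or 4, with adjusted p of up to 0.0643 and 0.105.

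Chance could not be excluded for the total of calls. Of the 35 splits of the 8 libraries into 4 and 4, 2 gave at least 70 genes, and the real split was 1 of these. The other gave 1027 genes, and all remaining splits gave 0. The split with 1027 genes set wild type 5, 6 and 8 with mutant 1 against wild type 7 with mutant 2, 3 and 4. It differs from the real split only by the exchange of mutant 1 and wild type 7. Genotype alone would not give more genes in this mixed split than in the real one. The 1027 genes therefore argue for a structure between these libraries apart from genotype. How far the 70 calls come from that structure was not tested. For gene lists, 4 of the 35 splits, the real split included, gave at least 15, and the highest other split gave 17.

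The rise of Hoxb1 is a pattern with several candidate explanations. Branchial motor neurons in the mutant sorts, which the gate on the Math1 reporter should remove, were argued against by 7 tested of 11 listed markers. Their median log2 fold change was -0.18 (SE of the mean 0.183), 0 passed with edgeR or DESeq2 or at an unadjusted p below 0.05, and the most abundant, Slc5a7, was at 5.93 CPM in wild type and 6.56 CPM in mutant libraries. The other tested markers had group means of at most 1.79 CPM, where the simulated test recovered few changes. The SE is over markers measured in the same libraries and does not cover the spread between libraries. A local effect of the engineered Hoxb2 allele on its neighbour and a loss of repression by Hox proteins cannot be told apart: 0 of 7 other tested genes around the Hoxb cluster passed with edgeR (Hoxb3os at an unadjusted p of 0.0435, and Hoxb3 passed without mutant 1), which a narrow local effect would also give, and every mutant library carries the allele.

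Of 69 placed called genes, 29 had another called gene within 5 Mb and farther than 100 kb, against a median of 19 in 10000 random sets matched on expression (random-set permutation p = 0.0293). Over windows of 1, 2, 5 and 10 Mb the random-set permutation p was 0.0185, 0.00950, 0.0270 and 0.0550. At an edgeR adjusted p below 0.1, 115 of 178 placed genes had such a neighbour within 5 Mb. The random median there was 98 (random-set permutation p = 0.0175). Chance placement was not excluded, because the p at 10 Mb did not pass and the windows were chosen after seeing the data. Co-regulation in 1 direction stays open, since 42.9% of 21 pairs went in opposite directions (95% binomial interval 21.8 to 66.0%). That interval takes the pairs as independent, although several share a gene, such as Cacna1g with Hoxb2 and with Hoxb1. It is therefore likely too narrow. Opposite directions lay close together on chromosome 4. There Zfp990 fell by 5.02 on the log2 scale (SE 0.412) and Padi4 by 3.77 (SE 0.394), whereas Zfp979 rose by 2.25 (SE 0.402). On chromosome 9, from 78182774 to 86695953, Gsta4 and Me1 fell whereas Irak1bp1 rose. Chromosome segments of another strain, carried with the engineered alleles, may contribute and stay open. Besides Hoxb1 and Hoxb2, calls within 10 Mb numbered 1 of 126 genes around Hoxa2 and 2 of 376 around Hoxb2. These were Pde1c near Hoxa2 and, near Hoxb2, Cacna1g among others. Such calls were not enriched (smaller Fisher exact p = 0.359), but they are too few for the test to decide. Segments elsewhere were not tested.

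At the preset correlation the cell cycle list passed as lower and the channel, receptor and vesicle lists as higher in mutants, but with an estimated correlation their adjusted p was 0.542 to 0.553. Gene length bias as the whole cause was argued against: a set test on the gene statistics alone, run before and after removing their trend on length and expression, called 12 of the 15 called lists and then 12. An axis that also varies between libraries of 1 genotype and a genotype effect on maturation cannot be told apart, since the library scores of 14 of the 15 lists overlapped between genotypes, which a modest genotype effect would also give. Sex make-up of the litters stays open: 14 of the 15 lists stayed called with the Y-linked level as a covariate, but that level differed by only -0.44 between genotypes (exact permutation p = 0.8). The covariate was also set mostly by wild type 8 and mutant 3, at -2.86 and -3.64 against at least 3.94 in the other libraries. It may therefore adjust little for differences that follow Xist. Without the 3 libraries lowest in Xist, wild type 5, wild type 6 and mutant 1, 11 lists passed, with fewer samples in the fit. The cell cycle, inhibitory neuron, synaptic adhesion, Hox and meningeal calls ended (camera adjusted p 0.0955, 0.0542, 0.069, 0.138 and 0.574). The Atoh1 lineage list passed as lower (0.0393).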
